A study of Mus musculus with 20 samples.

How the data were processed

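The series holds 20 samples of 18S rRNA from mouse embryonic fibroblasts, probed in living cells with DMS or left untreated. Per the labels' protocols, treated cells were kept in 0.5% DMS for 5 min and quenched, RNA was extracted and treated with DNase, and cDNA was made with 18S primers. An adaptor was then joined to the cDNA, followed by PCR. The labels name 4 kinds of reverse transcription, SSIII, AMV, TGIRT-II and one called Zhao, whose meaning they do not give. Of the samples, 16 carry a replicate letter, with 2 per group, and 4 carry none, namely SSIII without and with Mn2+, each untreated and with DMS.

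The deposited table gives, for each library and position, a stop fraction and a mutation fraction, and the same with the control library subtracted. Per the submitters' processing notes, cutadapt and Bowtie2 were used, with versions not given in the sources used here. The rule by which a read counted as a stop or a mutation, the denominator of each fraction, the reference sequence and any filter are also not given in the sources used here. A fraction that divides by reads passing a position depends on reads lost further along the RNA, and PCR copies of one cDNA count repeatedly, so the choice of these steps bears on every value. The deposited differences, which are neither fractions nor ratios because they can lie below 0, equalled the subtraction of the untreated from the DMS fraction to within 1e-09 percentage points. Differences were therefore computed from the deposited fractions, which were multiplied to percent.

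Libraries were matched to samples by name. The 4 used are the only ones of the table's Mn experiment, which holds 1 each of untreated, untreated with Mn2+, DMS and DMS with Mn2+, and the labels hold 1 sample without a letter for each. The table's names do not state the enzyme for these 4. It was taken from the sample titles. A further 25 library names were not used in any step, 16 of them on 18S (8 untreated and 8 DMS), whose names give neither enzyme nor letter, and 9 on Xist, a target outside the series. The tests fixed before the data were examined, count models with replicates, interactions between enzymes and permutations within enzymes, therefore could not be run. With 1 library per group and no read numbers there is also no interval. The depth of each library is unknown. The table gives no bases and no 18S sequence was used here, so groups by base, kinds of mutation and sites known by sequence were not analysed.

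All further choices were made after the data were seen. Positions 1 to 1559 were used, up to the first position at which a library lacks a stop value, out of 1840. A position lay in a stretch with many zeros where over 25% of the values within 25 nt were exactly 0 in any library and either readout. Differences are DMS minus untreated, or with minus without Mn2+, in percentage points, and a difference of 5 points was counted as large. The positions named adapt a rule fixed before the data were examined. For DMS differences and untreated values that rule was written per enzyme, and for DMS differences it required a passed test. Its use per metal state on the 4 libraries without a letter, with no test, was chosen after the data were seen. Only its part on differences between metal states was fixed for them. The positions named are the 6 highest and 3 lowest DMS differences per readout and metal state, the 3 highest untreated values, and the 6 largest differences of the DMS effect between metal states in each direction. A neighbour of 1248, positions from the list of shared leading positions and positions with a lower mutation part with Mn2+ were added after their values were seen. Overlaps used the 50 leading positions, with the number shared by independent lists as the square of 50 over the number of positions. The mutation part of the response used the 30 leading positions. The alternatives were all positions with values, positions outside stretches with many zeros, positions above 0 in all libraries, the median, leaving out the 10 most changed positions, a log2 ratio with a pseudocount of 0.1%, a difference scaled by the part of the control without an event, and 20 leading positions.

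The ranking of positions was tested on simulated data. With 50 positions raised by 5 points among 1559 and 2000 simulated reads at each position, 100% of them were recovered among the 50 leading positions, for stops and for mutations. That number of reads was assumed and says nothing of the real libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.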

Results

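Dimethyl sulfate (DMS) methylates bases of RNA that are not protected by pairing or by bound protein, and a reverse transcriptase that meets a methylated base may end the cDNA there or copy it with an error. The series recorded both outcomes on 18S ribosomal RNA, the RNA of the small ribosomal subunit, in mouse embryonic fibroblasts. The values described here come from 4 libraries made with the reverse transcriptase SSIII at 55 °C. Cells were untreated or exposed to 0.5% DMS for 5 min, and reverse transcription was done without or with added Mn2+, a metal ion known to make polymerases less accurate. Each of the 4 conditions had 1 library, so no value has a standard deviation, no difference could be set against a spread between replicates, and no p-value is given. The deposited values are a stop fraction and a mutation fraction at each position of the RNA, given here in percent. The numbers of reads were not given, so the exact depth behind each value is unknown and no counting interval is attached. Positions 1 to 1559 were compared, the part of the RNA before the first gap in the stop values. Position numbers are those of the deposited table, which gives no base and no genome coordinate. As a partial guide to depth, the share of values at exactly 0 among the positions within 25 nt is given where it passed 25%, taken as the highest share in any of the 4 libraries and either readout. Of the 1559 positions, 604 lay in such stretches. Most zeros were in the libraries with Mn2+. Stop fractions were 0 at 1.67% of positions untreated and 3.72% with DMS without Mn2+, and at 13.7% and 21.9% with it. A high share therefore says little about values without Mn2+. Between 601 and 800 the smallest stop fraction above 0 in untreated RNA was 0.0086% without and 0.303% with Mn2+. Differences with Mn2+ in such stretches can therefore rest on few events.

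The first comparison asked what Mn2+ did to the signal of RNA that had seen no DMS. The strongest stops of untreated RNA were far lower in the library with Mn2+. At position 1247 the stop fraction was 76.6% without and 7.37% with Mn2+, and at position 1248 it was 74.1% and 13.6%. The mutation fraction at 1248 went the other way, from 7.45% to 48.96%, the largest difference of all 1559 positions in that direction. At 1247 it was 0.380% and 0.639%. The next position, 1249, chosen after its values were seen, had stop fractions of 13.3% and 5.00% and mutation fractions of 0.0241% and 0.746%. Position 518 had stop fractions of 42.5% and 2.22%, with mutation fractions of 0.337% and 0.362%, in a stretch with up to 66.7% of values at 0.

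Over all positions, these sites included, the stop background was higher with Mn2+. The mean difference was 0.658 points, and 0.763 without the 10 most changed positions. The mean stop fraction over the 1559 positions was 0.877% in untreated RNA without Mn2+ and 1.53% with it, and the medians were 0.333% and 1.08%. The stop fraction was higher with Mn2+ at 1209 positions and lower at 330, and its mean was higher in 8 of 8 windows of 200 nt. With Mn2+ the highest stop fractions of untreated RNA were at positions 882 (19.5%), 808 (17.5%) and 286 (15.1%). The same positions without Mn2+ had 2.23%, 5.37% and 10.9%. Up to 31.4% of values around 808 were 0. Mean mutation fractions of untreated RNA were 1.07% without and 0.947% with Mn2+, a difference of -0.126 percentage points that became 0.00462 when stretches with many zeros were left out, so it has no settled direction. The highest mutation fractions of untreated RNA without Mn2+ were at positions 57 (14.4%), 272 (11.8%) and 1173 (10.1%). With Mn2+ they were 5.93%, 13.4% and 4.67%. Around 57 and 1173, up to 51.0% and 31.4% of values were 0 in a library with Mn2+.

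**Figure D1:**
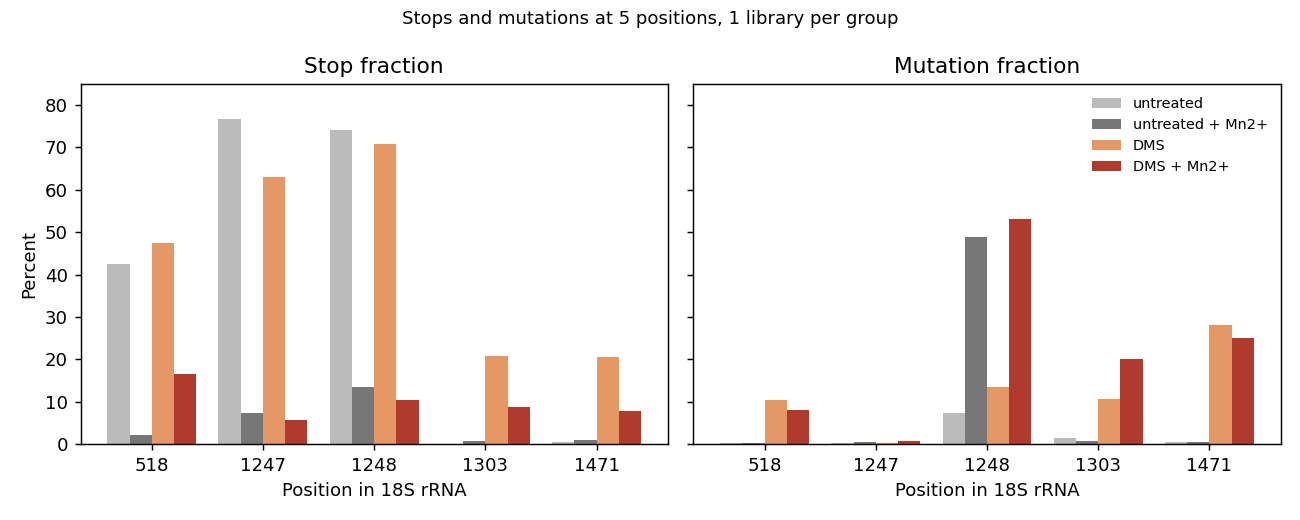
Stop fraction (left) and mutation fraction (right), in percent, at 5 positions of 18S rRNA, with 1 bar for each of the 4 libraries. In untreated RNA the stop bars at 1247 and 1248 are 76.6% and 74.1% without Mn2+ and 7.37% and 13.6% with it, and the mutation bar at 1248 is 48.96% in untreated RNA with Mn2+ against 7.45% without.

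The second comparison asked where DMS changed the readouts without Mn2+. Stops were higher by large amounts at a small set of positions. The stop fraction was at least 5 percentage points higher in the DMS library at 31 positions and at least 5 points lower at 4. Position 1197 had the largest difference, from 1.58% to 27.9%, followed by 869 (1.61% to 26.7%), 569 (0.605% to 23.5%), 461 (0.903% to 23.1%), 361 (6.67% to 27.7%) and 1303 (0.0520% to 20.9%). Position 569 lay in a stretch with up to 70.6% of values at 0 in a library with Mn2+. In the libraries compared here, stop fractions were 0 at 0.5% of positions 401 to 600 untreated and at 2.5% with DMS. The largest differences in the other direction were at 1247 (76.6% to 63.0%), 449 (22.7% to 11.2%) and 485 (17.5% to 7.02%), all sites of strong stops without DMS. Over all 1559 positions the mean difference was 0.214 percentage points, or 0.101 without the 10 most changed positions, and the median was -0.0317, so that most positions were not higher with DMS. The stop fraction was higher at 617 and lower at 925.

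Mutations without Mn2+ passed the same 5 points at fewer positions. Rises of at least 1 point were seen at 96 positions in mutations and 127 in stops, and any rise at 796 and 617. The readouts may not share a denominator, so equal thresholds need not be equally strict. The mutation fraction was at least 5 points higher with DMS at 7 positions, 4 of them outside stretches with many zeros, and at least 5 points lower at 0. Position 1471 had the largest difference, from 0.571% to 28.0%, followed by 142 (0.378% to 19.6%), 518 (0.337% to 10.4%), 1303 (1.36% to 10.8%), 836 (0.410% to 7.51%) and 565 (0.299% to 6.54%). Up to 25.5%, 66.7% and 74.5% of values around 142, 518 and 565 were 0 in a library with Mn2+. Without Mn2+, mutation fractions were 0 at 0.0% of positions 401 to 600 in both libraries. Over 1 to 200 they were 0 at 1.0% of positions untreated and 2.0% with DMS. The lowest differences were -3.78 points at 216, -3.33 at 1304 and -3.15 at 87, and up to 43.1% of values around 87 were 0 in a library with Mn2+. The mean difference was 0.110 percentage points. It was 0.0469 without the 10 most changed positions and the median was 0.00384.

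The third comparison asked the same of the libraries made with Mn2+. The positions that led outside stretches with many zeros were 1197, 1303 and 1471 in both readouts. Their stop fractions were 1.27% untreated and 10.2% with DMS at 1197, 0.817% and 8.89% at 1303, and 1.07% and 7.90% at 1471. Their mutation fractions were 0.872% and 14.8%, 0.677% and 20.1%, and 0.529% and 25.1%, in the same order. Position 836 had mutation fractions of 0.376% and 7.54%, close to those without Mn2+. The largest stop difference of all, 32.1 points at position 580, and those of 14.4 at 518, 10.1 at 560 and 8.63 at 142 lay where up to 66.7%, 66.7%, 76.5% and 25.5% of values were 0. For mutations, the same holds for 15.5 points at 142, 12.1 at 39 and 9.59 at 1174, with up to 25.5%, 62.7% and 31.4% at 0. The stop fraction was at least 5 points higher with DMS at 14 positions, of which 4 were outside such stretches. The mutation fraction was at least 5 points higher at 20 positions, of which 5 were outside them. At least 5 points lower were 2 positions in stops and 6 in mutations. The lowest stop differences were -11.8 points at 882, -10.4 at 37 and -4.76 at 512, and up to 64.7% and 54.9% of values around 37 and 512 were 0. The lowest mutation differences were -16.1 points at 638, -8.33 at 626 and -8.33 at 634, where up to 84.3%, 82.4% and 84.3% of values were 0. Mean differences were 0.0429 percentage points in stops and 0.0659 in mutations. Without the 10 most changed positions they were -0.00553 and 0.0207, and both medians were 0. Without stretches with many zeros they were 0.0172 and 0.181, and at positions above 0 in all 4 libraries 0.123 and 0.280. The last setting selects on the values compared. With Mn2+, mutation fractions of 0 were at 318 positions with DMS and 174 untreated, so leaving them out can raise the difference.

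**Figure D2:**
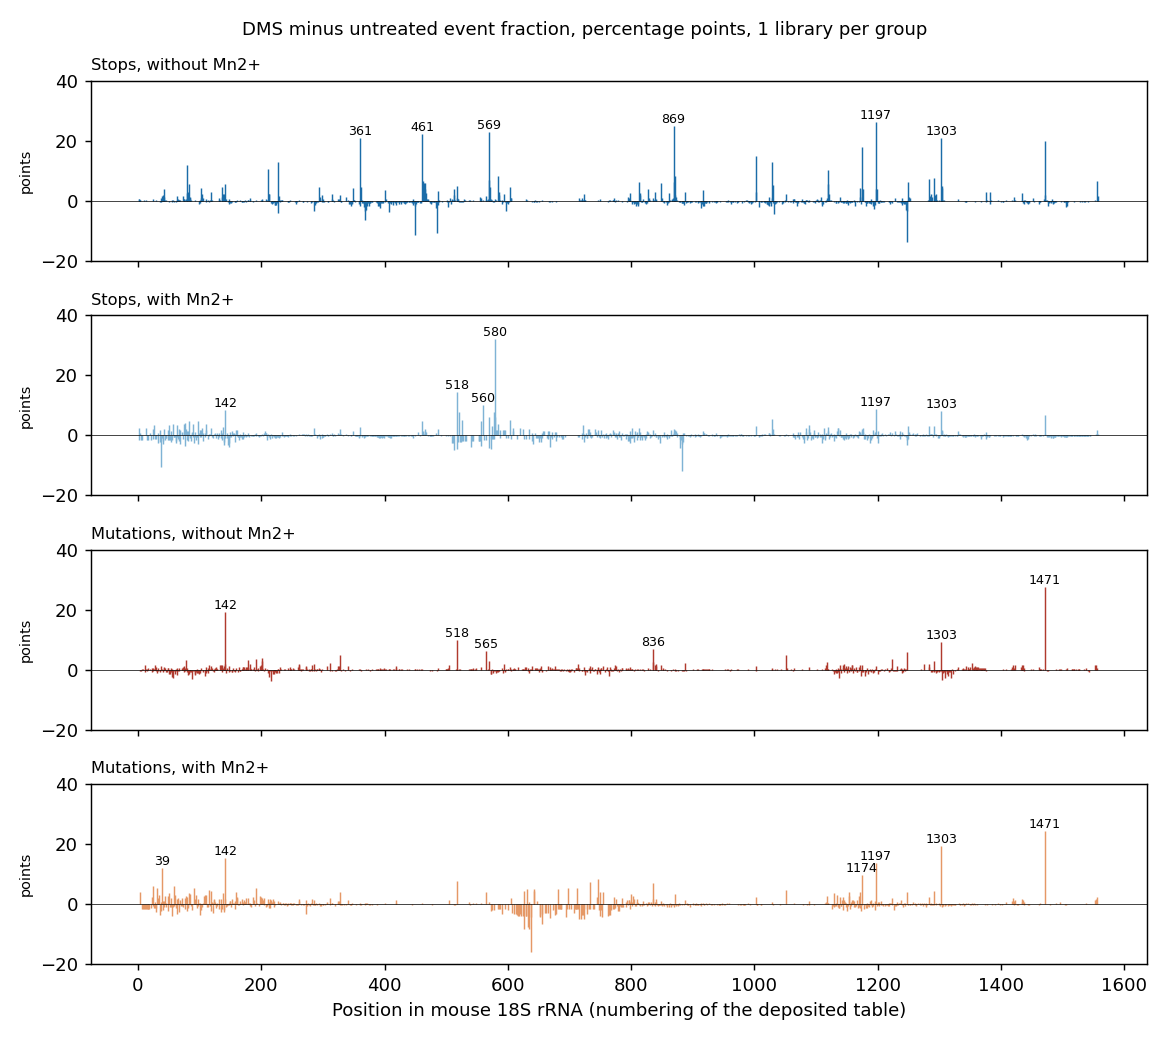
Difference between the DMS and the untreated library in percentage points (vertical axis) at each of the 1559 positions of 18S rRNA (horizontal axis), for stops and mutations without and with Mn2+, with 1 line per position and the 6 highest positions of each panel numbered. Stops without Mn2+ reach 26.3 points at 1197, while mutations reach 27.5 points without and 24.5 points with Mn2+ at 1471.

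The fourth comparison set the DMS response without Mn2+ against that with Mn2+. For the 30 positions with the largest response, summed over both readouts and both metal states, the rise in stops and the rise in mutations were added and the part seen as mutations was taken, with a fall counted as 0. That part had a median of 10.0% without Mn2+ and 59.5% with it. It was higher with Mn2+ at 22 of the 30 positions and lower at 7. Among the 17 of these positions outside stretches with many zeros it was higher at 15 and lower at 2, and among the 13 others it was higher at 7 and lower at 5. The mean stop difference over the 30 positions was 10.5 points without and 4.79 with Mn2+, and the mean mutation difference was 3.47 and 5.13. These positions were chosen by the same differences from which the part was computed. Stops without Mn2+ had the largest mean among them, so the choice favours a low mutation part without Mn2+. The higher part with Mn2+ is therefore not free of selection. Stops and mutations may not share a denominator, which the sources used here do not give, so the part is a description and not a share of reads.

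Single positions differed in this respect. At 1197 the DMS difference in stops was 26.3 points without and 8.93 with Mn2+, and in mutations 1.16 and 13.9. At 1303 it was 20.9 and 8.07 in stops and 9.39 and 19.4 in mutations. At 1174 it was 17.9 and 2.00 in stops and 1.74 and 9.59 in mutations. At 1471 stops differed by 20.0 and 6.83 points while mutations differed by 27.5 and 24.5. Positions 869, 461 and 361 had stop differences of 25.05, 22.2 and 21.0 points without Mn2+ and of 1.20, 4.94 and 2.75 points with it. Their mutation differences were at most 0.498 points in either state. The mutation part was lower with Mn2+ at 836 (86.8% without and 81.0% with) and at 327 (69.8% and 63.5%), and in stretches with many zeros at 142 (76.9% and 64.2%), 518 (67.1% and 34.9%), 569 (11.2% and 10.5%), 560 (16.5% and 0.3997%) and 604 (17.7% and 0%). At 580 it was 0% in both states. The 6 largest differences between metal states in the DMS effect on mutations were taken in each direction. Except at 1197, 1303 and 1174, they lay where over 50% of nearby values were 0. The effect without and with Mn2+ was 0.803 and 8.33 points at 747, -0.490 and 6.10 at 59, 0.478 and -7.69 at 632, -0.727 and -6.45 at 655, and 1.07 and -4.44 at 669. Position 216, not among these, also differed by over 5 points, with -3.781 without and 1.415 with Mn2+. It lay outside stretches with many zeros.

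**Figure D3:**
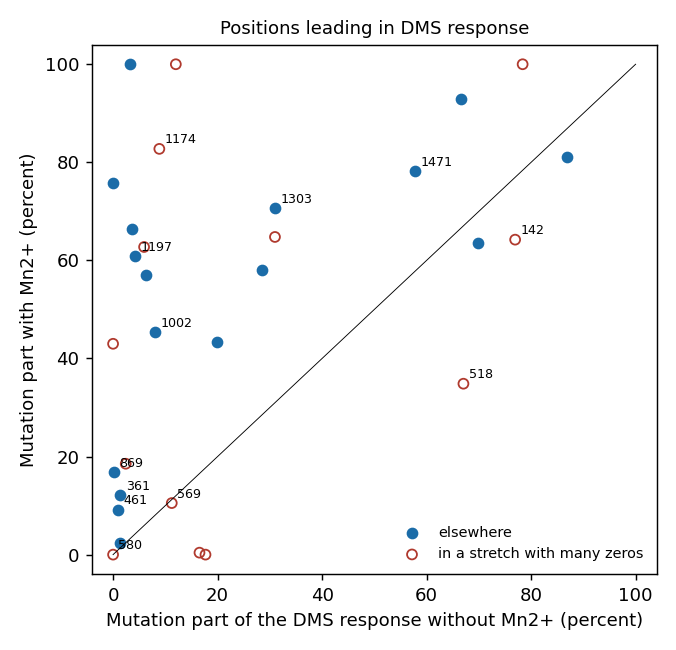
Part of the DMS response seen as mutations, in percent, without Mn2+ (horizontal axis) and with Mn2+ (vertical axis), with 1 point for each of the 30 positions with the largest response, open where over 25% of nearby values were 0, and the first 12 positions numbered. The line marks equal parts, and 22 of the 30 points lie above it. The positions were chosen by the same differences from which the parts were computed.

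The last comparison asked whether stops and mutations marked the same positions. Of the 50 positions with the largest DMS difference in stops and the 50 in mutations, 10 were shared without Mn2+ and 11 with Mn2+, where lists drawn independently would share 1.60. Without and with Mn2+, the lists of stops shared 19 positions and those of mutations 13. These numbers depended on the setting. Ranked by log2 ratio, stops and mutations with Mn2+ shared 3 positions, close to the 1.60 of independent lists, and the lists of stops shared 6. At positions above 0 in all 4 libraries, stops and mutations with Mn2+ shared 22 and the mutation lists 24, where independent lists would share 2.42. Without stretches with many zeros, stops and mutations shared 11 positions without Mn2+ and 13 with it. The lists of stops then shared 26 and those of mutations 32, where independent lists would share 2.62. The number for independent lists takes all positions as equally likely to lead, which uneven depth along the RNA would break. On all 4 lists were 5 positions, 142, 518, 1292, 1303 and 1471. Across positions, which are not independent replicates, the DMS differences in stops and in mutations had Pearson r = 0.296 and Spearman rho = 0.0530 without Mn2+, and r = 0.212 and rho = 0.0520 with Mn2+. At positions above 0 in all 4 libraries the first rho was 0.0822. Without the 10 positions most changed in stops in the same metal state, r was 0.134 and 0.133. Positions extreme in mutations alone were not left out. When the mutation values were moved along the RNA by up to 4 nt in either direction, the correlation was highest with no shift, and r at the other shifts without Mn2+ lay between -0.0675 and 0.0542.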

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

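All comparisons in this part were chosen after the data were seen, and none of the differences between metal states was tested, since each group had 1 library. The values are listed because the DMS effect had one sign without Mn2+ and the opposite sign with it. The single positions were chosen for an extreme fall in 1 metal state, so a smaller difference in the other follows from the choice. Some values of opposite sign were slight, such as 0.081 points at 449. The signs are therefore not read as a reversal.

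At single positions, the DMS difference in stops was -11.458 points without and 0.081 with Mn2+ at 449, -10.486 and 0.254 at 485, and 1.942 and -4.762 at 512. In mutations it was -3.781 and 1.415 at 216, 0.131 and -8.333 at 626, and 0.082 and -16.071 at 638. Up to 54.9%, 82.4% and 84.3% of values around 512, 626 and 638 were 0, and up to 7.8% around the other 3 positions.

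In windows of 200 nt, the mean DMS difference in stops was 0.397 points without and -0.01 with Mn2+ over positions 1 to 200, 0.063 and -0.024 over 201 to 400, 0.104 and -0.023 over 601 to 800, 0.148 and -0.085 over 801 to 1000, and 0.091 and -0.063 over 1401 to 1559. In mutations it was 0.095 and -0.784 over 601 to 800. With Mn2+, 56.0% of the mutation fractions in that window were 0 in untreated RNA and 85.5% with DMS, and of its stop fractions 52.5% and 66.5%. Over positions 1 to 200 the stop fractions with Mn2+ were 0 at 15.5% and 39.0% of positions, in the same order, and over the other 3 windows named at 1.00% or less.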

How the results depend on the processing

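All alternatives reported here were chosen after the data were seen. The one at positions above 0 in all libraries also selects on the values compared. Those fixed earlier (coverage minimum, weighting, scaling of counts, other count tests, stop offset by base, leaving out a lettered library) were not run, because the table holds no counts or bases and the lettered libraries could not be matched. No paired analysis was possible because the groups used share only 1 replicate number. An additive fit of DMS and Mn2+ over the 4 libraries, which would take their interaction as error, was not run. Depth is unknown, so "same" means within 1.5 times. Of 106 alternative values for 22 results, 72 stayed within that, 29 moved further and 5 changed sign; for those that moved or changed sign the cause was not tested unless stated.

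The higher stop background with Mn2+, the 31 positions with higher stops without Mn2+ and the mutation part of the response stayed within 1.5 times under each alternative run on them. For the last this is weak evidence: the position sets overlap, sharing 28, 17 and 25 of 30 positions with the set reported, and 4 of the 5 sets tried had the same pair, 1292 and 1197, in the middle, which fixes the median at 59.5%.

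Without stretches with many zeros, which leaves fewer positions, the mean difference of stops with Mn2+ was 0.0172 and of mutations with Mn2+ 0.181. Positions 5 points higher were 4 in stops with Mn2+, 4 in mutations without and 5 in mutations with Mn2+. The Mn2+ difference in mutations changed sign, to 0.00462 untreated and 0.0598 with DMS, and mutation lists shared 32 positions. At positions above 0 in all libraries these means were 0.123 and 0.280, the counts with Mn2+ were 9 in stops and 11 in mutations, the Mn2+ difference in mutations was -0.0754 untreated and changed sign to 0.0595 with DMS, lists shared 22 (stops and mutations with Mn2+) and 24 (mutations), and Spearman rho was 0.0822 in place of 0.0530 between stops and mutations without Mn2+ and 0.308 in place of 0.187 between stops without and with Mn2+. With the median, stops without Mn2+ changed sign to -0.0317, stops and mutations with Mn2+ were 0, mutations without Mn2+ 0.00384, and the Mn2+ difference in mutations -0.0168 and -0.0574. Without the 10 most changed positions, stops were 0.101 without Mn2+ and changed sign to -0.00553 with it, and mutations were 0.0469 and 0.0207. With log2 ratios, stops and mutations with Mn2+ shared 3 positions and the stop lists 6. With 20 leading positions, by construction fewer, the shared numbers were 4 and 5 between readouts without and with Mn2+, 6 between stop lists and 6 between mutation lists.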

Other observations

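All tests in this part were chosen after the values were seen, so they can argue against an explanation but cannot establish one. No biological difference between groups of cells was tested.

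With Mn2+, position 1248 had fewer stops and more mutations, in untreated RNA and with DMS (stops 70.7% and 10.4%, mutations 13.4% and 53.2% without and with Mn2+). A variant or reference mismatch would give one mutation fraction in both metal states, if its denominator left out reads that stopped there. The smaller of the 2 ratios was 3.96. That denominator is not given, and with stopped reads in it the mutation fraction would rise as stops fell. The ratio therefore cannot decide on a variant. A general increase of mutations with Mn2+ is argued against by median changes over positions of -0.0168 points at most, and few reads at the site by a gap between libraries of one metal state of at most 5.99 points, against at least 39.7 between metal states. A naturally modified base is a candidate explanation, since human 18S rRNA is known to carry a hypermodified uridine at the position of that number. It stays open: the 74.1% of stops without DMS would go with it, but neither the base nor the numbering was checked here.

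Position 1561, outside the range compared and in a stretch without stop values, had mutation fractions of 98.9%, 98.9%, 97.5% and 97.6% in untreated RNA without and with Mn2+ and with DMS without and with Mn2+. A fixed difference between the sequenced molecules and the reference and a modified base are both candidate explanations, and neither was decided. The range over the 4 libraries was 1.42 points and the larger change with Mn2+ was 0.0687 points, but the position was chosen for its high values and had at most 2.49 points left to rise, so that a small range and a small change were bound to be seen.

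Between positions 601 and 800, stop fractions were 0 at 52.5% and 66.5% of positions in the libraries with Mn2+, untreated and with DMS, and at 4.00% and 6.50% without it. Fewer reads behind the Mn2+ libraries there may account for it, since the smallest stop fraction above 0 was at least 35.2 times higher with Mn2+. A lower stop fraction there is argued against by the mean, which was higher with Mn2+ by 0.338 points in untreated RNA and by 0.210 with DMS (standard errors over the 200 positions 0.0523 and 0.0641, which are not errors between libraries). The median there was 0.114% in untreated RNA and 0.152% with DMS without Mn2+, and 0% in both with it. With most values at 0 such a median follows, so it does not decide between the explanations. The number of reads itself is unknown.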
